A study of Rattus norvegicus with 6 samples.

How the data were processed

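RNA from cultured brainstem cells of spontaneously hypertensive rats (SHR) and of normotensive Wistar Kyoto rats (WKY) was hybridised to single-colour CodeLink rat bioarrays, 3 arrays per strain. Per the labels, each sample was RNA of cells pooled from 3 dishes, and the series design text calls the 3 hybridisations of a strain biological replicates. The labels do not say whether the 3 pools of a strain came from different litters or culture days, so the p-values measure the spread between these pooled samples. The number of arrays limits the precision of every value.

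Per the labels' design text, the authors extracted background-subtracted spot intensities with the CodeLink Expression Analysis software, left out measurements under the negative controls plus 2 SD, kept genes measured on all 3 arrays of at least 1 strain, and normalized the arrays by the quantile method. Versions are not given in the sources used here. The intensities were deposited in 2 forms. The per-sample tables hold linear intensity with medians between 439 and 571, not normalized between arrays although their titles call them normalized, and a code of -9999 stands for between 178 and 238 spots per array. What the code means is not stated. The series table holds the submitters' quantile normalized intensity, with the same median of 520 in all 6 columns and the same rank order as the per-sample tables (Spearman correlation 1.0). Of its values, 95.5% were whole multiples of 1/12 of the last decimal of the per-sample tables, within a tolerance of 0.1 of that decimal, against 48.3% for 1/6, as a mean over 12 arrays would give. The arrays beyond these 6 were not used here. The code entered that mean as a value, so the 615 lowest entries of each column are not above 0. The filter on negative controls could not be seen in either form.

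The series table was the main source, because the design fixed before the data were examined took the values as deposited after quantile normalization. The list of alternatives fixed at the same time named the sources the other way round, with the per-sample tables first, and they were therefore run as the alternative. Centring each array on its median would leave the series table unchanged, so this and cyclic loess were run on the per-sample intensities. Values not above 0 were set to missing and log2 was taken with no offset. Probes were kept with 3 valid values in one strain and at least 2 in the other, which left 33249 probes for testing and 600 untested. A further 1280 spots of the per-sample tables have no row in the series table and were not used.

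Probes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), SHR minus WKY, two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of adjusted p 0.05. For gene lists, limma's camera was run with a preset correlation of 0.01 over the lists with at least 5 measured genes, using the brightest complete probe of each gene, and was repeated with an estimated correlation and with fry. Array scores of a list are means of its genes' log2 values, each gene centred on its mean over the 6 arrays. For 40 fixed lists, 970 of 1151 entries had a probe with 1 gene symbol. Of the probes in the series table, 16753 have 1 symbol in the platform annotation, 165 have several and 16931 have none. Entrez identifiers of 16724 probes were found in the gene table of assembly GRCr8, which updated 1 symbol. No probe with several symbols was named, and no coordinates are given because the files name no genome build. Figures were drawn with matplotlib 3.10.9.

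The genes named were chosen by a rule fixed before the data were examined. With no probe past the threshold, the rule takes the 12 genes per direction with the smallest unadjusted p (brightest probe of a gene), said not to pass, up to 4 passing members and up to 2 others of each list by smallest p, a fixed set of genes of catecholamine, angiotensin, neuropeptide and adenosine signalling with genes of earlier SHR literature, and up to 5 genes per direction measured in one strain only. Other genes are said to be chosen after their values were seen. Of the fixed set, Tubb3, Xist and Ddx3y had no probe with that single symbol.

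The steps were tested on simulated data with the means of these 33249 probes and 200 changed probes. The spreads of the probes were dealt out to them at random, and the arrays were independent. In the real data dim probes spread more than bright ones, so the shares called need not hold there. The limma test called 21.9% of probes changed 2-fold, 68.6% of those changed 4-fold and 72.7% of those changed 8-fold, with 10 unchanged probes called. A list of astrocyte markers shifted by 0.50 (log2) in simulated independent genes was called, and no other list was. Genes of the real lists can be correlated, with an estimate of 0.55 for oligodendrocyte markers, so this outcome need not hold there.

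Alternatives covered the normalization, the source of values, the probe filter, dim probes, an offset of 55.5 intensity units before log2, the variance model, array weights, the threshold, the replicate number as a block, the list test and leaving out each array. The test of 1 probe per named gene and a quantile normalization over the 6 arrays done here were added after seeing the data.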

Results

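Expression was measured in cultured brainstem cells of the spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, and of the Wistar Kyoto rat (WKY), its normotensive control strain. Each strain had 3 arrays, each made with RNA of cells pooled from 3 dishes. The median signal per array lay between 439 and 571 intensity units before normalization between arrays. After the submitters' normalization, correlations across probes were 0.969 to 0.979 between arrays of one strain and 0.964 to 0.977 between arrays of different strains. The comparison asks which transcripts differ between the hypertensive and the normotensive strain in cultured brainstem cells. Its values are log2 intensities, given as SHR minus WKY.

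Gene lists that stood higher in SHR by camera with a preset correlation were those of fibroblasts and meningeal cells, extracellular matrix, and the ependyma and choroid plexus, and lists of the oligodendrocyte lineage, GABA and glycine transmission, and inflammatory cytokines stood lower. None of these 6 of 39 lists passed with an estimated correlation, where the smallest adjusted p was 0.886, or with fry. Other splits of the 6 arrays into 3 and 3 gave up to 9 lists. The median difference was 0.64 (0.41 to 0.84 over the alternatives) for the fibroblast and meningeal list and -0.87 (-1.34 to -0.56) for the oligodendrocyte list. Among single genes, Aldh1a2, which makes retinoic acid and is a marker of meningeal cells, was 2.81-fold brighter in SHR. Trap1, a mitochondrial chaperone, was 13.3-fold brighter in WKY. Each of these genes had 1 probe tested. No single probe passed the adjusted threshold.

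Of the 33249 probes tested with limma, 0 passed an adjusted p of 0.05, and 2545 (7.65%, against 5% by chance) had an unadjusted p under 0.05, 1212 of them higher and 1333 lower in SHR. The smallest adjusted p was 0.0528, at 5 probes. The 3 SHR values lay wholly above or below the 3 WKY values at 13.8% of probes, where chance gives 10%. With such separation and a difference of at least 4-fold there were 20 probes higher and 36 lower in SHR. Alternative settings called up to 28 probes, with an intensity trend and a robust prior in limma, and a test of 1 probe per named gene, added after seeing the data, called 9 of 12082 genes.

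The 9 genes called by that added test were Mrps27, Trap1, Abcb10, Mmadhc, Runx1, Nt5c3a, Chmp1b and Mylk, lower in SHR, and Aldh1a2, higher in SHR. They are also among the genes with the smallest unadjusted p over all probes, where none passed. Trap1 had a log2 signal of 8.91 ± 0.38 (SD, n = 3) in SHR and 12.63 ± 0.32 in WKY, a difference of -3.73 ± 0.25 (SE). Mrps27, a protein of the mitochondrial ribosome, differed by -2.50 ± 0.17, and Abcb10, a transporter of the inner mitochondrial membrane, by -3.04 ± 0.23. Mmadhc, which acts in intracellular cobalamin trafficking, differed by -3.80 ± 0.29, Runx1, a transcription factor of blood cell development, by -3.68 ± 0.32 (-3.02 with an offset before log2), Nt5c3a, a pyrimidine nucleotidase, by -3.25 ± 0.29, and Chmp1b, a component of the ESCRT machinery, by -3.29 ± 0.32. Mylk, the myosin light chain kinase, differed by -1.63 ± 0.17, and its other probes gave -1.10 and -0.59. The second probe of Mrps27 gave 0.27 ± 0.17, against the direction of the first. Nr1i3, a nuclear receptor of xenobiotic metabolism (-3.08 ± 0.36), Homer2, a postsynaptic scaffold protein (-1.06 ± 0.13), Strbp (-1.96 ± 0.29, with 0.58 at its other probe) and Prom2 (-1.23 ± 0.15, measured on 2 SHR arrays, and -0.59 with an offset before log2) completed the 12 lower genes. Of these 12, all but Mrps27, Mylk and Strbp had 1 probe tested, so no second probe could check them.

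Aldh1a2 had the smallest unadjusted p of the genes higher in SHR, with 11.92 ± 0.14 (SD, n = 3) in SHR, 10.43 ± 0.15 in WKY and a difference of 1.49 ± 0.14 (SE). The others of the 12 included Tpm1, a tropomyosin (0.92 ± 0.13, and 0.54 at its other probe), Col26a1, a collagen (1.37 ± 0.20, and 1.07 at its other probe), Zfp597 (1.02 ± 0.14), the lectin Clec2d (1.40 ± 0.21) and Lrif1 (3.43 ± 0.56, and 2.75 without WKY 1). Slc13a4, a sulfate transporter (1.79 ± 0.28), and Mycbpap (1.36 ± 0.20) also stood higher, but the other probes of Slc13a4 gave -0.59 and -0.17 and that of Mycbpap gave -0.18. C14h5orf52 (1.45 ± 0.22), Sult2a1 (1.34 ± 0.20, measured on 2 SHR arrays, and 0.057 with median-centred per-sample intensities) and Kcnmb1 (0.88 ± 0.14, with -0.54 at its other probe and 0.55 with an offset) had dim spots in both strains. The SHR 3 entry of Sult2a1 was not above 0 and was left out. Read as a low signal, it would go against the higher value in SHR. None of the genes higher in SHR passed over all probes. Aldh1a2, Zfp597, Clec2d, Lrif1, C14h5orf52 and Sult2a1 had 1 probe tested each.

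**Figure D1:**
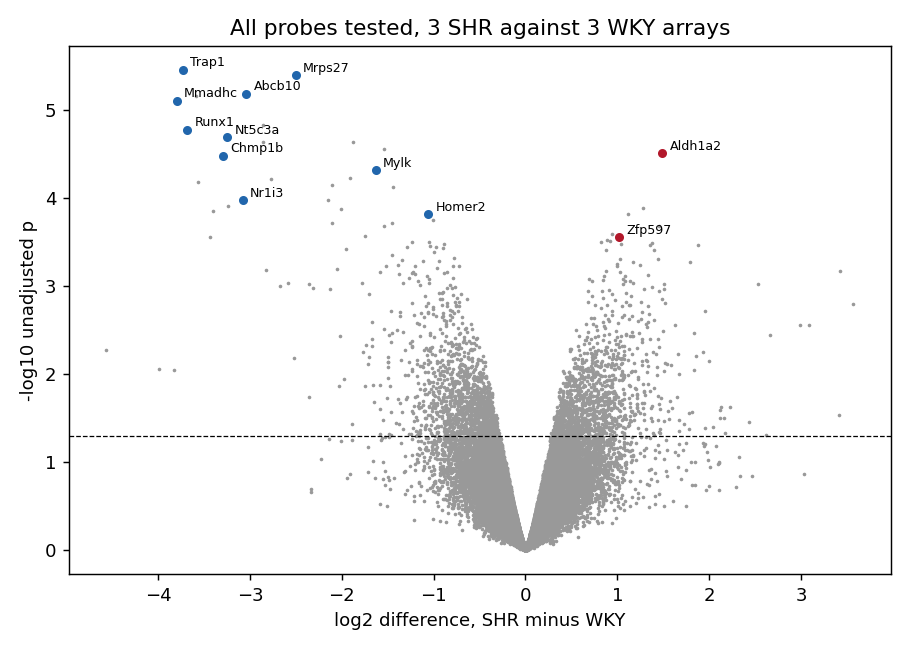
Each point is 1 of the 33249 probes, with its log2 difference (SHR minus WKY) on the horizontal axis and -log10 of its unadjusted p on the vertical axis, the dashed line marking an unadjusted p of 0.05. The 12 labelled genes are those with the smallest unadjusted p among genes named by the rule, 10 of them lower in SHR (blue) and 2 higher (red), Trap1 at -3.73 and Aldh1a2 at 1.49.

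The list of fibroblast and meningeal markers stood higher in SHR, with 11 of 14 measured genes above 0 (camera adjusted p = 0.000158, and adjusted p = 0.886 with an estimated correlation). Its leading members were Aldh1a2 and Slc6a13, a GABA transporter of the meninges (1.62 ± 0.34), which were the 2 members past adjusted p 0.05 adjusted over the list alone, while 0 passed over all probes. The proteoglycans Lum (1.46 ± 0.58) and Dcn (1.24 ± 0.50), chosen after their values were seen, also stood higher. The collagen genes Col1a1 (-0.02 ± 0.17) and Col1a2 (0.20 ± 0.16), chosen in the same way, differed little. Igf2 (-0.39 ± 0.19) and Thy1 (-0.25 ± 0.52) were, with Col1a1, the members below 0. Array scores of the list were -0.0015, 0.44 and 0.51 in SHR and -0.40, -0.13 and -0.41 in WKY, with no overlap. The extracellular matrix list, which shares 6 measured genes with it, had 36 of 50 genes above 0 and a median difference of 0.18, between 0.11 and 0.35 over the alternatives (adjusted p = 0.000158, and adjusted p = 0.886 with an estimated correlation). Col6a2, a chain of collagen VI, differed by 1.06 ± 0.18 and was the 1 member past the threshold adjusted over the list alone, and Lama1, a laminin chain, differed by 0.87 ± 0.21.

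Ependymal and choroid plexus markers had a median difference of 0.75, between 0.27 and 1.20 over the alternatives, with 7 of 9 genes above 0 (adjusted p = 0.0342, and adjusted p = 0.886 with an estimated correlation). Ttr, the transthyretin gene that the choroid plexus transcribes strongly, differed by 2.66 ± 0.60 (2.09 without WKY 1 and 3.27 without WKY 3). It was the 1 member past the threshold adjusted over the list alone. Otx2, a transcription factor of the choroid plexus, differed by 1.47 ± 0.47 (0.95 without WKY 1 and 0.88 with an offset before log2). The members below 0 were Drc12 (-0.88 ± 0.71) and Kl (-0.29 ± 0.27), chosen after their values were seen. Array scores were 0.43, -0.16 and 0.84 in SHR and -0.14, -0.77 and -0.19 in WKY, with SHR 2 within the WKY range. The call of this list was lost without SHR 1, SHR 3 or WKY 2 and in 4 of 5 normalization settings.

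Oligodendrocyte lineage markers stood lower in SHR, with 16 of 17 genes below 0 (adjusted p = 0.000158, and adjusted p = 0.886 with an estimated correlation). Enpp6, a marker of newly formed oligodendrocytes, differed by -1.51 ± 0.48 and Mobp, a myelin protein gene, by -1.46 ± 0.51, and 0 members passed adjusted over the list alone or over all probes. The myelin genes Mbp (-1.01 ± 0.44) and Mog (-1.03 ± 0.49) were chosen after their values were seen. So were Olig1 (-0.04 ± 0.13), Olig2 (-0.08 ± 0.14) and Cnp (-0.10 ± 0.13), which count among the genes below 0 but differed little. Pdgfra was the 1 gene above 0, at 0.37 ± 0.16. Array scores were -0.62, 0.32 and -0.78 in SHR and 0.32, 0.53 and 0.23 in WKY, so that SHR 2 lay within the range of the WKY arrays. Medians of other cell type lists that did not pass included -0.08 for microglia and macrophages, -0.02 for astrocytes and -0.18 for neurons. They also included 0.13 for endothelial cells and pericytes and -0.26 for smooth muscle (camera adjusted p = 0.0594 for smooth muscle, and 0.886 with an estimated correlation).

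Genes of GABA and glycine transmission had a median difference of -0.17, between -0.29 and -0.08 over the alternatives, with 19 of 22 below 0 (adjusted p = 0.00212, and adjusted p = 0.886 with an estimated correlation). Gabrb2, a GABA receptor subunit, differed by -0.75 ± 0.18 at its brightest probe and by 0.46 ± 0.31 at the other, and Slc6a13 differed in the opposite direction. These were the 2 members past the threshold adjusted over the list alone. Array scores were -0.25, 0.088 and -0.13 in SHR and 0.048, 0.11 and 0.13 in WKY, with SHR 2 within the WKY range. The call was lost without SHR 1. The inflammatory cytokine and chemokine list had 29 of 39 genes below 0 and a median of -0.17, which was -0.0029 with unnormalized intensities (adjusted p = 0.0342, and adjusted p = 0.916 with an estimated correlation). Tnfrsf1b, a receptor of tumor necrosis factor, differed by -0.55 ± 0.23 and Cxcl12, a chemokine, by 0.59 ± 0.22 (0.38 without SHR 2). Its array scores overlapped, at -0.14, 0.16 and -0.35 in SHR and -0.12, 0.011 and 0.43 in WKY, and those of interferon response genes were -0.18, 0.29 and -0.45 in SHR and -0.99, 0.53 and 0.79 in WKY. No member passed adjusted over the list alone, and the call was lost without SHR 1, SHR 3 or WKY 3 and in 1 of 5 normalization settings. Neuronal markers had array scores of -0.25, 0.18 and -0.20 in SHR and -0.03, 0.27 and 0.03 in WKY.

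**Figure D2:**
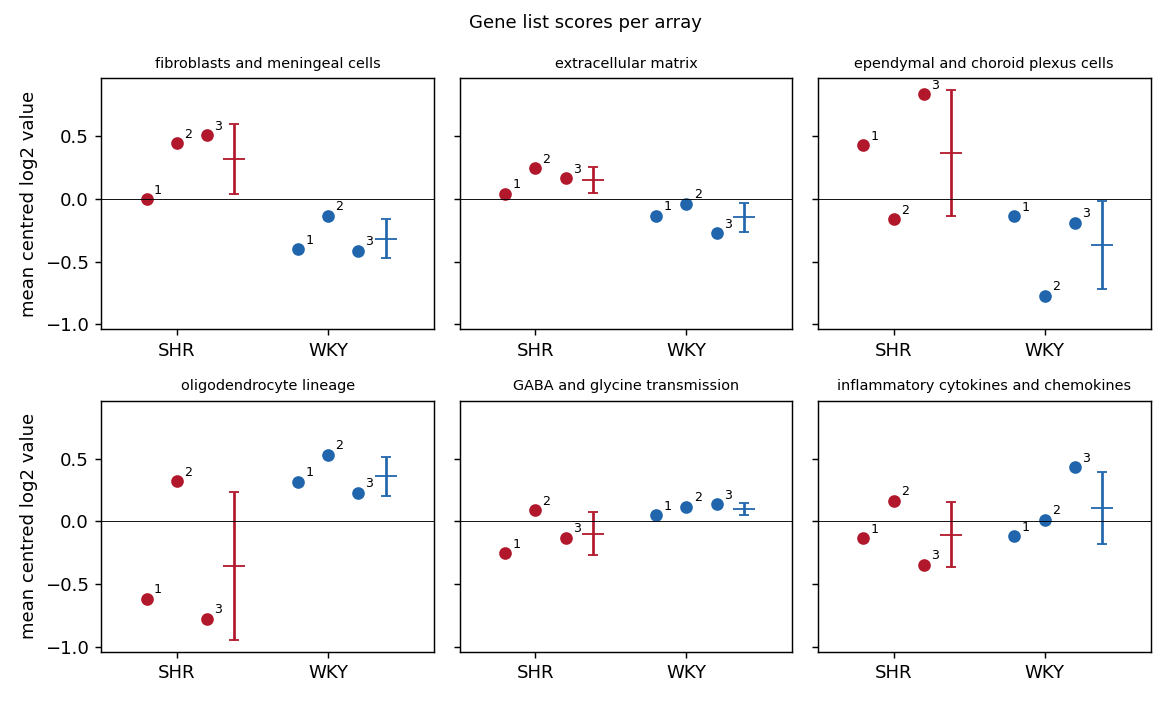
Points give the score of each array (mean log2 value of the list's genes, each gene centred on its mean over the 6 arrays) for SHR and WKY arrays numbered 1 to 3, and the bars beside them give the mean and SD (n = 3) for the 6 lists that passed camera with the preset correlation. The scores of the strains do not overlap for the fibroblast and meningeal and the extracellular matrix lists and overlap for the other 4, where SHR 2 lies among the WKY arrays, at 0.32 for oligodendrocyte markers.

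Lists of the systems that control blood pressure did not pass. The renin-angiotensin list had a median of -0.03. Agtrap, which binds the angiotensin receptor, differed by 1.66 ± 0.41 (1.15 and 0.33 at its other probes). Agt, the angiotensinogen gene, differed by -0.81 ± 0.20 (adjusted p = 0.516 over all probes in limma). Agtrap and Agt were the members past the threshold adjusted over the list alone, 1 higher and 1 lower, while 0 passed over all probes. The median of the catecholamine list was 0.02, with Ddc at 0.44 ± 0.29 (0.16 without SHR 3), Th at 0.01 ± 0.14 and Dbh at 0.09 ± 0.11. Adrenergic and dopamine receptors had a median of -0.04 and nitric oxide and cyclic GMP genes one of 0.08, with Gucy1b1, a subunit of soluble guanylate cyclase, at -1.24 ± 0.29, the arginase gene Arg2 at 0.58 ± 0.18 (0.33 at its other probe) and Nos1 at -0.01 ± 0.17.

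The neuropeptide list had a median near 0, with 4 members lower and 0 higher at an unadjusted p under 0.05. Its leading members were Adcyap1r1, a receptor of the peptide PACAP, at -0.93 ± 0.22 (-0.26 and -0.52 at its other probes) and Nppa, the atrial natriuretic peptide gene, at -1.18 ± 0.30. Avp, the vasopressin gene, chosen after its values were seen, gave -1.16 ± 0.47. Npy differed by -0.59 ± 0.22, Npy1r by 0.13 ± 0.17 (other probes 1.27 and -0.05) and Npy2r by -0.19 ± 0.24. For adenosine receptors, Adora1 gave 0.04 ± 0.14 (-0.26 at its other probe) and Adora2a 0.03 ± 0.17 (-0.32 at its other probe). Among genes with SHR differences in earlier literature, Ephx2, the soluble epoxide hydrolase gene, was brighter in SHR (2.00 ± 0.51, and 1.40 without WKY 1, adjusted p = 0.527 in limma), while Cd36 (-0.31 ± 0.19, and -0.76 ± 0.45 at its other probe), Acsm3 (-0.32 ± 0.33) and Gstm1 (0.12 ± 0.11) differed by less. Gfap, the astrocyte filament gene, gave -0.05 ± 0.18. The small differences of Th, Nos1, Npy1r, Adora1, Adora2a, Acsm3 and Gfap turned direction in at least 1 alternative. Those of Cd36, Npy2r, Dbh and Gstm1 moved in size.

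At 1 gene, Tmem50b, all 3 SHR arrays held the missing code while the WKY arrays measured 3777, 2151 and 2603 intensity units, so no fold is given. At 1 unnamed probe the series table held 81.6, 67.5 and 62.8 units in SHR and values not above 0 in WKY, where the per-sample intensities were -0.31, 24.0 and 7.77, with no missing code.

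For genes with several probes, separated differences of at least 4-fold were mostly seen at 1 probe. Of the genes with a separated probe of at least 4-fold, 12 had another probe tested, and these genes were chosen after their values were seen. The large difference had an unadjusted p under 0.01 in limma at 5 of them. At others it was imprecise, as for Atg14 (2.47 ± 1.49, and 0.15 ± 0.29 at its other probe). Lcp1, a leukocyte actin-bundling protein gene, gave -2.05 ± 0.33 at one probe and -0.15 ± 0.15 at the other, Apol3l1 gave -2.11 ± 0.23 and -0.18 ± 0.20, and Fgfr2, a fibroblast growth factor receptor, gave 2.99 ± 0.64 (2.32 without WKY 1) and -0.28 ± 0.18. Mobp was the exception, with -2.02 ± 0.45 at one probe and -1.46 ± 0.51 and -0.23 ± 0.60 at the others.

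**Figure D3:**
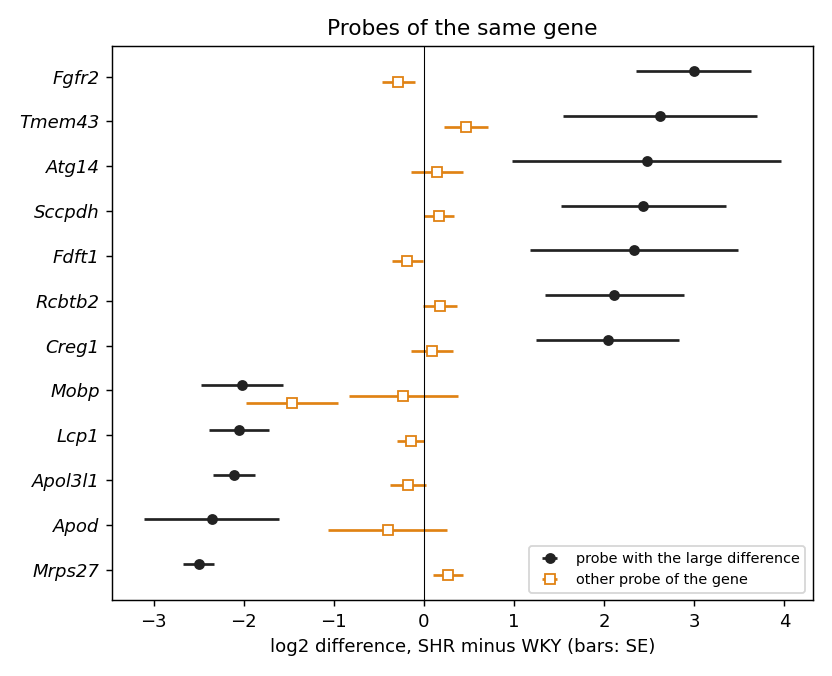
For 12 genes with a probe of at least 4-fold separated difference, the filled point gives the log2 difference (SHR minus WKY, horizontal axis) at that probe and open squares give the other probes of the gene, with bars for SE. For 11 of the genes the other probes average under 33.3% of the large difference or point the other way. The other probes of Mrps27 (0.27 against -2.50), Fgfr2 and Fdft1 point the other way. Mobp has another probe at -1.46.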

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

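No probe passed in the main setting, and the count of probes past the threshold moved with the choices. It was 28 (3 higher and 25 lower in SHR, 27 of them at least 2-fold) with an intensity trend and robust prior, 18 without the dimmest 25% of probes, 17 with an offset, 13 at an adjusted p of 0.10, 5 with probes valid on all 6 arrays and 5 with array weights. All probes called in the last 5 settings were also at least 2-fold. It was 9, all at least 2-fold, with 1 probe per named gene, an alternative added after seeing the data that tests fewer probes, and 992 genes then had an unadjusted p under 0.05. With every normalization alternative, at an adjusted p of 0.01 and without each array in turn it stayed at 0. With the replicate number as a replicate block 0 probes passed and 2798 had an unadjusted p under 0.05. Deviations of same-numbered arrays from their strain means correlated at -0.0017, 0.21 and -0.12. Those of other pairs across the strains lay between -0.23 and 0.25. So few values cannot show whether same-numbered arrays were prepared together. Unnormalized intensities split probes of unadjusted p under 0.05 into 1542 higher and 846 lower, and median-centred ones into 902 and 1791, against 1212 and 1333. The median difference of all probes was 0.12 (log2) in the unnormalized intensities and -0.0099 in the series table. The count of called gene lists was 6, and was 0 with an estimated correlation, also with WKY 1 left out (added after seeing the data), 0 with fry, 10 with unnormalized intensities, 9 with the replicate block, and between 3 (without SHR 1) and 10 (without SHR 2) without single arrays. The fibroblast and meningeal, extracellular matrix and oligodendrocyte lists passed in all 6 fits that left out an array and in all 5 normalization settings. Unadjusted p under 0.05 occurred at 1824 to 3573 probes without single arrays. Measured in one strain only were 5 probes when 2 valid values were enough. The causes of these changes were not tested. The median residual SD was 0.48 (log2) in the dimmest 25% of probes and 0.16 in the brightest 25%.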

Other observations

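The fits of the interferon list, with and without single arrays, were planned, and the choice to describe them and all other tests in this part came after the results they bear on were seen. Interferon response genes differed more between arrays than between strains. The mean score of the 21 measured genes was -0.18, 0.29 and -0.45 in SHR and -0.99, 0.53 and 0.79 in WKY, and their estimated inter-gene correlation was 0.845, the highest of the lists. Mx1, an antiviral GTPase gene chosen after its values were seen, had log2 signals of 13.24, 14.22 and 12.96 in SHR and 12.29, 14.78 and 15.01 in WKY. The list did not pass for the strain comparison (camera adjusted p = 0.428, median -0.30), but did without WKY 1 (median -0.73, adjusted p = 1.44e-07, where the other alternatives reached up to 0.993). With an estimated correlation its adjusted p was 0.920 on all arrays and, in a fit added after seeing the data, 0.793 without WKY 1. Its median was 0.047 without WKY 3, -0.059 without WKY 2 and -0.098 without SHR 3, so its direction rests on single arrays.

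The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For probes past the threshold, and for those at least 2-fold, the real split gave 0 and the highest of the others 0, and with a real count of 0 all 10 splits must give as many, which says nothing about chance. At an unadjusted p under 0.05 the real split gave 2545 probes and the highest other 4719, and 2 splits, the real one included, gave as many. With an intensity trend and robust prior the real split gave 28 probes and the highest other 880, again with 2 splits, the real one included, giving as many. With 1 probe per named gene the real split gave 9 genes and the highest other 0, with 1 split, the real one, giving as many. For gene lists the real split gave 6 and the highest other 9, and 5 splits, the real one included, gave as many. Separated probes of at least 4-fold numbered 56 in the real split and 17 in the highest other, with 1 split, the real one, giving as many. The split with 4719 and 880 probes, found as the highest of the 10 and not tested further, set SHR 1, SHR 3 and WKY 1 against the other 3 arrays. A count of 880 against 28 points to a structure of the samples that crosses the strains. In the main limma fit the same split gave 0 probes past the threshold (smallest adjusted p = 0.145). It gave 17 separated probes of at least 4-fold, against 56 in the real split.

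Large strain differences at single probes were weighed first. If the whole transcript differed, the other probes of these 12 genes should share the difference. Their median, signed by the large probe, was 0.16 (95% interval -0.18 to 0.40), under 1 log2 unit. For these 12 genes as a set this argues against a shared difference of that size, while smaller shared differences stay open. Genes under the 4-fold bar were not covered, and the probes of some, such as Mylk and Agtrap, shared a direction. In 11 genes the other probes averaged under 33.3% of the large difference, which a difference at the probe's own target would give, but so would noise in genes picked for 1 extreme probe, so both stay open. For noise, 19 probes had an unadjusted p under 1e-04 in the real split and 14 in the highest other split, where chance gives 3.32. That highest split was again SHR 1, SHR 3 and WKY 1 against the rest, and the remaining splits gave between 0 and 2. Separated probes of at least 4-fold numbered 56 against 17. The 10 splits are too few to decide. A sequence variant between the strains was not tested.

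Higher fibroblast and meningeal markers with lower oligodendrocyte markers in SHR were weighed second. A lower share of neurons or astrocytes would raise both lists alike, and their scores moved apart by 1.35 ± 0.34 (SE). A lower share of oligodendrocytes would raise all other types alike. The fibroblast and meningeal score was higher by 0.68 ± 0.17 than the mean of neurons, astrocytes, microglia and endothelial cells. Both lists were picked for their opposite directions on these same arrays, so these outcomes were largely set by that choice. Neither comparison can exclude its explanation. Cultures that differ in makeup whatever the strain were considered for the oligodendrocyte part. The widest range within a strain was 1.52 times the strain difference, which that explanation allows. That range was 1.09 in SHR, against 0.30 in WKY and a strain difference of -0.72. A wide range in SHR alone, with 3 arrays, cannot decide, so the explanation stays open. For the fibroblast and meningeal part the ratio of range to strain difference was 0.803, which decides nothing. A biological difference between the strains stays open and untested.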
